A study of Mus musculus with 4 samples.

How the data were processed

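4 Drop-seq libraries of MMTV-PyMT mammary tumours of mice were used, 2 labelled FoxM1 DD/DD and 2 labelled FoxM1 +/+, each with a replicate number in its title. Per the labels' protocols, tumours were chopped and digested with collagenase and DNase, red cells were lysed, the cell suspension was strained and run on Drop-seq, and libraries were made by Nextera XT tagmentation. Per the submitters' processing notes, STAR and FastQC were used with GRCm38.p5, and per the labels' protocols the PyMT and Cre sequences were added to the mouse genome. The deposited values are whole-number counts per gene and barcode, not normalised; the counter, its version, how barcodes were selected and whether counts were collapsed by molecular identifier are not given in the sources used here. The files hold 17986, 17994, 17971 and 17982 barcodes for WT1, WT2, DD1 and DD2, and 80.9%, 82.9%, 77.9% and 80.1% of their values above 0 equal 1.

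Barcodes with at least 500 counts, at least 300 genes and at most 20% of counts on mitochondrial transcripts were kept. Scrublet, run on each library with an expected rate of 5%, marked 1 of 7414 barcodes in WT1, 5 of 1846 in WT2, 9 of 3498 in DD1 and 2 of 752 in DD2. These were left out, but a caller that marks so few cannot be taken to have removed the doublets, so the gene counts and shares were also computed without the 5% of barcodes with the highest scores, an alternative chosen after seeing the data. The kept cells held 9119296, 2714051, 6060598 and 1783171 counts. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 were used with scanpy 1.11.5, over the 4 libraries without batch integration. Clusters were called by hand from their leading genes and fixed marker genes.

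Counts of each class were summed per library, the library being the replicate. edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, genes kept by filterByExpr) was the main test in R 4.3.3, and adjusted p-values are Benjamini-Hochberg. DESeq2 1.42.0 was the alternative. Each SE given with an edgeR log2 fold change is that change divided by the root of its F statistic, not a fitted standard error. The fitted standard errors of DESeq2 were larger, for example 0.73 against 0.52 for Gpnmb over all cells and 0.60 against 0.53 for PYMT in macrophage-like cells. The test ran where each library held at least 20 cells of a class, so all cells, the epithelial-like class and the macrophage-like class were tested. The planned tests of fibroblast-like, T cell-like and neutrophil-like classes were not run because too few DD cells were found, and that of endothelial cells because no cluster was called so. Marker genes, 25 gene lists and the rule for named genes were fixed before the data were examined. The lists were tested with camera (preset correlation 0.01) and fry in limma 3.58.1, where at least 5 members were measured; the macrophage-like list tests were added after seeing the data. No list passed fry at an adjusted p under 0.05. Shares of cells were compared by exact permutation tests with 95% Wilson intervals, and the difference of the genotype effect between the classes by an edgeR interaction term with the library as a block, chosen after seeing the data.

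Over all cells and in the epithelial-like class the rule takes genes past the threshold with a mean of at least 20 CPM and both DD libraries on 1 side of both WT libraries, the 10 largest log2 fold changes per direction, as named genes. Other classes take 4 per direction. If fewer than 3 passed in a direction, the 3 with the smallest p are given as not passing, and that applied throughout. Foxm1, Rb1, PyMT and Cre features are always given over all cells where present, and test values within a class where they passed the low-count filter. Up to 4 members with the smallest p are given for each list described. The rule names no predicted genes, pseudogenes, Y-linked genes or Xist, and genes named outside it are marked as chosen after their values were seen.

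The gene, list and interaction tests were tested on simulated data with known changes, where lists moved by design were called and 0 of 20 random lists were. The simulated genes varied independently of each other, so this does not test the list calls where genes move together. Alternatives were DESeq2, other size factors, no filter on low counts, the replicate number as a block, each library left out, 300 and 1000 counts as the minimum, doublets kept, 10% mitochondrial counts, thinning to the smallest library total, and Leiden resolution 0.5. Gene coordinates are from the GENCODE annotation of GRCm38.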

Results

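Single-cell RNA profiles were collected by Drop-seq, a droplet method that tags the RNA of each cell with a bead barcode, in 4 samples of mouse mammary tumours driven by MMTV-PyMT, the polyoma middle T oncogene under the MMTV promoter. The samples are of end point tumours, 2 labelled FoxM1 DD/DD (DD1 and DD2) and 2 labelled FoxM1 +/+ (WT1 and WT2). The series concerns the link between FoxM1, a transcription factor of the cell division programme, and the retinoblastoma protein in shaping the cells around the tumour; the labels do not describe the DD change itself. The labels do not state separate animals or tumours, so p-values measure only the spread between these samples. Total counts were 12480301 in WT1, 5682141 in WT2, 8321773 in DD1 and 3023489 in DD2. After filtering, 7413 cells of WT1, 1841 of WT2, 3489 of DD1 and 750 of DD2 were kept, with median counts per cell of 878, 914, 1142 and 1488.

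Foxm1 RNA was scarce in all 4 libraries. The gene lies on chromosome 6 at 128362967 to 128376146 of GRCm38, on the plus strand. Summed over all kept cells, 31 counts were found in WT1, 7 in WT2, 8 in DD1 and 2 in DD2, which is 3.40, 2.58, 1.32 and 1.12 CPM of the summed counts, with 95% Poisson intervals of 2.31 to 4.83, 1.04 to 5.31, 0.570 to 2.60 and 0.136 to 4.05. The log2 fold change, DD against WT, was −1.14 ± 0.78 (SE, n = 2 per genotype), with an adjusted p of 0.836 in the edgeR quasi-likelihood test. In epithelial-like cells alone Foxm1 was at 3.63, 1.29, 1.35 and 1.17 CPM in WT1, WT2, DD1 and DD2, so the genotypes overlapped. The labels do not say that the DD change alters RNA level, and these counts do not check the genotype. Rb1, the retinoblastoma gene, on chromosome 14 at 73183673 to 73325822, had 30.8, 21.4, 9.24 and 19.6 CPM in WT1, WT2, DD1 and DD2, a log2 fold change of −0.79 with an adjusted p of 0.830. The PyMT transgene (feature PYMT) had 1738, 3380, 2750 and 2179 CPM in the same order, a log2 fold change of 0.06 with an adjusted p of 0.994, which was −0.37 without WT1 and −0.19 without DD1. No feature named Cre was found.

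Clustering gave 11 clusters, which were called from their leading genes and from marker genes. Clusters 0 and 3 were macrophage-like, with C1qa, C1qb and C1qc among the 10 leading genes of cluster 0, behind MHC class II genes such as Cd74 and H2-Eb1, and with Lyz2 and the dendritic cell marker Ccr7 among those of cluster 3. Clusters 1, 2, 4, 5, 6 and 10 were epithelial-like. Cluster 7 was called T cell-like for Trbc2 and Cd3g, but cytotoxic genes shared with NK cells, such as Gzmb, Gzma and Nkg7, were ahead of these in it and 47.0% of its cells held Cd3g, so NK cells are not set apart from this class. Cluster 8 was fibroblast-like, with Col3a1 and Col1a2, and the pericyte gene Rgs5 was also among its leading genes. Cluster 9 was neutrophil-like, with S100a8 and S100a9. No cluster was called endothelial-like.

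Macrophage-like cells, the phagocytes of the tumour, and T cell-like cells had smaller shares in both DD libraries than in both WT libraries, and epithelial-like cells had larger ones. The macrophage-like share was 32.0% in WT1 and 17.9% in WT2 against 2.55% in DD1 and 7.60% in DD2, with means of 24.9% ± 9.92 and 5.08% ± 3.57 (SD, n = 2), a ratio of 4.91. The T cell-like share was 3.86% (3.44% to 4.32%) and 3.42% (2.68% to 4.35%) in WT1 and WT2 against 0.229% (0.116% to 0.452%) and 0.933% (0.453% to 1.91%) in DD1 and DD2. Epithelial-like cells were 56.3% (55.2% to 57.5%) and 78.0% (76.1% to 79.8%) against 97.2% (96.6% to 97.7%) and 91.2% (89.0% to 93.0%). Ranges in brackets are 95% Wilson intervals. For the macrophage-like share these were 30.9% to 33.0% and 16.2% to 19.7% for WT1 and WT2, and 2.08% to 3.13% and 5.91% to 9.72% for DD1 and DD2. Fibroblast-like cells made up 5.37% of WT1 and 0.489% of WT2, 0.0573% of DD1 and 0.133% of DD2, and neutrophil-like cells 2.48% of WT1, 0.163% of WT2 and 0.133% of DD2, with 0 of 3489 cells in DD1, which allows a share of up to 0.0860% taken as 3 counts of the total, with an upper Wilson limit of 0.110%.

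In the exact permutation test each of these 5 differences had a two-sided p of 0.333, the smallest that 2 against 2 libraries allow. In an edgeR quasi-likelihood test of cell numbers, the log2 change of the macrophage-like class was −2.31 and that of the T cell-like class −2.75, each with an adjusted p of 0.103, as had fibroblast-like (−5.13) and neutrophil-like cells (−5.19); for epithelial-like cells it was 0.546. The macrophage-like difference, DD minus WT, was −19.9 percentage points and −12.8 without WT1, and the fibroblast-like and neutrophil-like differences were −0.394 and −0.0963 without WT1 against −2.83 and −1.26 with it. With a minimum of 300 counts per cell the neutrophil-like shares overlapped, at 3.85% and 0.400% in WT1 and WT2 against 0.0186% and 1.04% in DD1 and DD2 (exact permutation p = 0.667), and the difference was 0.126 without WT1. Intervals here cover counting error only. The libraries differed in depth, with median counts of macrophage-like cells at 917, 758.5, 1064 and 899 in WT1, WT2, DD1 and DD2 under a minimum of 500 counts per cell. Barcodes under 300 counts, outside the kept cells, carried 3220 and 2598 CPM of the macrophage marker genes in WT1 and WT2 and 1023 and 1464 CPM in DD1 and DD2. These barcodes numbered 4624, 14459, 12585 and 17003 in WT1, WT2, DD1 and DD2, so the cutoff took a different part of each library.

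**Figure D1:**
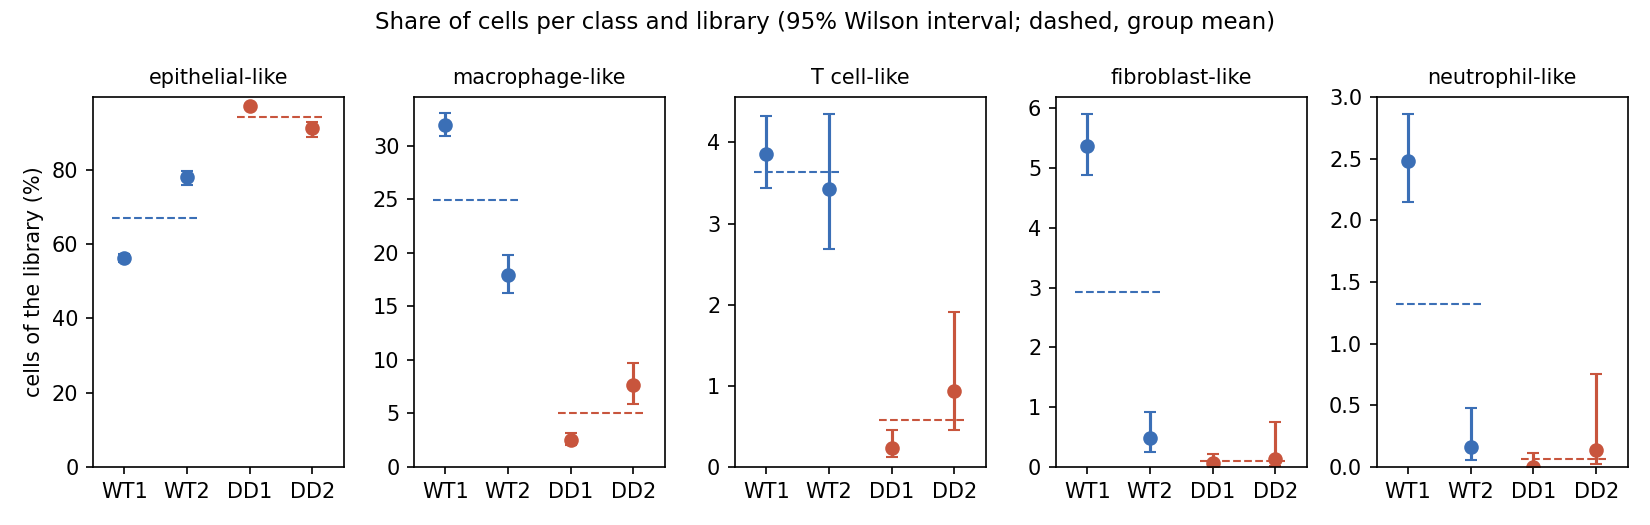
Share of cells of each class in each library, as percent of the kept cells, with 95% Wilson intervals and dashed lines for the group means. Both DD libraries lie below both WT libraries in the macrophage-like share (2.55% and 7.60% against 32.0% and 17.9%) and above them in the epithelial-like share.

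The share of epithelial-like cells with G2/M transcripts, the genes of late cell division that FoxM1 is known to regulate, overlapped between the genotypes under the planned rule and moved with the count settings. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, and Cks1b, a partner of cyclin-dependent kinases, had log2 fold changes of 0.91 and 0.77 in this class, with an adjusted p of 0.981 in edgeR. Anln and Prc1, also among the 4 members of the G2/M list with the smallest p, went the other way, at −0.68 and −0.51 in DESeq2. The G2/M and mitosis list did not pass in camera there, at an adjusted p of 0.889, with 18 of 32 members higher. After thinning each cell to 500 counts, 10.1% of epithelial-like cells in WT1 and 6.75% in WT2 carried at least 2 counts of the G2/M list, against 7.58% in DD1 and 7.31% in DD2. Means were 8.43% ± 2.37 and 7.45% ± 0.192 (SD, n = 2), and the exact permutation test gave p = 1. No epithelial-like cell was too shallow for this thinning. Without thinning the shares were 20.2%, 18.4%, 17.0% and 20.6%. With at least 1 count in place of 2 they were 28.7% and 22.4% in WT1 and WT2 against 19.8% and 19.4% in DD1 and DD2. In cells thinned to 1000 counts they were 19.1% and 13.3% against 11.5% and 11.9%, which left out 2351, 735, 1480 and 205 shallower cells of WT1, WT2, DD1 and DD2. With a minimum of 300 counts per cell and thinning to 300 they were 6.62% and 5.17% against 4.60% and 5.11%. In these 3 settings the exact permutation test gave p = 0.333, the smallest it can give. Cells of at least 1000 counts, thinned to 500, overlapped, at 11.1% and 6.99% in WT1 and WT2 against 7.23% and 7.10% in DD1 and DD2. With at least 3 counts the shares were 5.63% and 3.97% in WT1 and WT2 against 4.75% and 5.41% in DD1 and DD2, and the difference turned to 0.281 (exact permutation p = 1). The same share was 9.75%, 8.18%, 8.99% and 10.5% in macrophage-like cells with Wilson intervals that overlapped those of epithelial-like cells in each library. In T cell-like cells it was 14.7%, 15.9%, 12.5% and 14.3%, on only 8 and 7 cells in DD1 and DD2. Neutrophil-like cells of WT1 had 15.8% (29 of 184, 11.2% to 21.7%), above epithelial-like cells of WT1 (9.23% to 11.1%). A class planned as one that should cycle little was thus not lower, so the rule is not shown to pick out dividing cells. Median depths were 893, 986, 1145 and 1628.5 counts in epithelial-like and 917, 758.5, 1064 and 899 in macrophage-like cells of WT1, WT2, DD1 and DD2. The difference, DD minus WT, was −0.985 percentage points and turned to 0.691 without WT1.

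Summed over all cells, most members of the macrophage, cytotoxic, CC chemokine and MHC class II lists had lower values in the DD libraries. The interferon response and MHC class I lists did not pass in camera, and no single gene passed the threshold in edgeR. Gpnmb, a transmembrane glycoprotein of macrophages on chromosome 6 at 49036546 to 49070929, had a log2 fold change of −5.23 ± 0.52 (SE, n = 2 per genotype), with 69.7 and 52.4 normalised CPM in WT1 and WT2 and 1.25 and 2.27 in DD1 and DD2. The cytotoxic granule proteases Gzma and Gzmb had log2 fold changes of −5.03 ± 0.54 and −3.63 ± 0.44. Higher in DD were Snrpc, a spliceosome component (1.94 ± 0.41), Spry1, an inhibitor of growth factor signalling (1.96 ± 0.42), and Col9a1, a collagen (2.14 ± 0.46). Each of these 6 genes had an adjusted p of 0.471 in edgeR and separated both DD from both WT libraries. In DESeq2 all 6 passed, with adjusted p from 8.93e-09 (Gpnmb) to 0.0483 (Spry1).

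**Figure D2:**
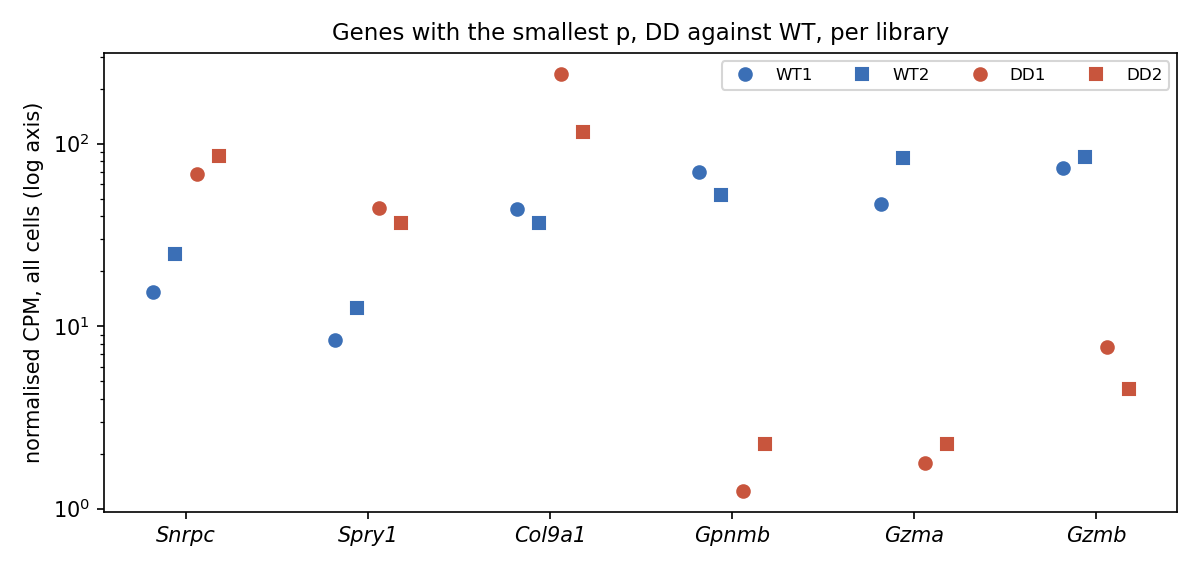
Normalised CPM over all cells (log axis) of the 3 genes per direction with the smallest p, 1 point per library. For Gpnmb both DD libraries (1.25 and 2.27) lie below both WT libraries (69.7 and 52.4), while Snrpc, Spry1 and Col9a1 lie higher in DD.

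Of 14230 genes tested over all cells, edgeR called 0 at an adjusted p under 0.05, with 973 at an unadjusted p under 0.05, and DESeq2 called 257, of which 37 were higher and 220 lower in DD. The edgeR count was 702 without DD2, 40 without DD1 and 2 without WT1, namely Igkc and 2310057J18Rik, which were chosen after their values were seen. In simulated data of this size, the test called 29.0% of genes changed by 2 on the log2 scale and 77.0% of those changed by 3, and 10.9% of its calls were false.

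Of the 25 lists fixed beforehand, 11 were lower in DD over all cells by camera with its preset correlation, and 0 of them held with an estimated correlation. The sum mixes cell types, so these list tests cannot tell lower shares of macrophage-like and T cell-like cells from lower expression per cell. No member of the lists passed per gene in edgeR, while DESeq2 called members such as Gzma (adjusted p = 1.16e-08), Trem2 (2.34e-07) and Il1b (9.70e-06). Among the 7 measured cytotoxic and exhausted lymphocyte genes, 7 had lower values in DD, and the camera adjusted p was 1.08e-21 (adjusted p = 0.315 with an estimated correlation). Nkg7 (−3.05) and Havcr2 (−3.41) were members besides Gzma and Gzmb, and adjusted over the list alone 7 of the 7 passed. The 14 measured alternative macrophage genes all had lower values, with a median log2 fold change of −2.87, including Trem2 (−3.85) and Apoe (−3.05), a lipid carrier; the camera adjusted p was 1.08e-21 (0.437 with an estimated correlation), and adjusted over the list alone 10 passed. All 12 inflammatory macrophage genes were lower as well, with a median of −3.51 and with Il1a (−3.93), a cytokine, and Nlrp3 (−3.79), an inflammasome sensor, at a camera adjusted p of 1.54e-20 (0.437 with an estimated correlation). Adjusted over the list alone, 10 passed.

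Chemokine and MHC class II lists followed the same direction over all cells, where the share of macrophage-like cells was also lower. Within macrophage-like cells the median log2 fold change of MHC class II genes was 0.35, with 7 of 7 higher. For CC chemokines it was −0.05 there, with 4 of 9 higher, and for CXC chemokines −0.54, with 1 of 5 higher. Of 10 measured CC chemokines, 9 were lower, among them Ccl4 (−3.28), Ccl7 (−2.59), Ccl12 (−2.97) and Ccl6 (−2.96), with a camera adjusted p of 5.96e-15 (0.437 with an estimated correlation) and 8 passing adjusted over the list alone. Of 8 MHC class II genes, all had lower values, including H2-DMa (−2.64) and H2-Ab1 (−2.79), at 5.03e-10 (0.437 with an estimated correlation), with 5 passing adjusted over the list alone. The CXC chemokines Cxcl10 (−3.74) and Cxcl2 (−2.69) belonged to a list of 10 measured genes, 8 of them lower, with an adjusted p of 1.77e-04 (0.556 with an estimated correlation), which was lost without DD1 at 0.426. Cytokines and colony factors had Il1b at −3.94 and an adjusted p of 3.09e-04 (0.556 with an estimated correlation); without DD1 it was 0.0601. The angiogenesis list, with Nrp1 at −2.33, had an adjusted p of 1.52e-04 (0.556 with an estimated correlation) and 0.114 without WT1.

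Stromal lists were lower in the all-cell sum. Of 21 collagen and matrix genes, 20 had lower values, with Col1a2 at −4.31 and Sparc at −4.99, and the camera adjusted p was 6.16e-16 (0.437 with an estimated correlation), with 8 passing adjusted over the list alone. The mesenchymal list, with Vim at −2.42 and Zeb2 at −2.96, had an adjusted p of 1.21e-09 (0.448 with an estimated correlation), and the basal keratin and contractile list, with Tagln at −5.53 and Acta2 at −2.57, 2.58e-08 (0.437 with an estimated correlation). Lists of G2/M and mitosis genes (adjusted p = 0.808, 17 of 32 higher), G1/S and E2F targets (0.098), interferon response (0.234), MHC class I (0.124), hypoxia and glycolysis (0.705), dissociation stress (0.584), oxidative stress defence (0.171), unfolded protein response (0.098), ribosomal proteins (0.0581) and mitochondrial transcripts (0.700) did not pass in camera. Milk and secretory (0.236), luminal progenitor (0.234), hormone-sensing luminal (0.0895) and epithelial adhesion (0.0784) genes did not pass either. The macrophage-like and T cell-like shares were lower in the same libraries, at 2.55% and 7.60% and at 0.229% and 0.933%, as was the fibroblast-like share, at 0.0573% and 0.133% in DD1 and DD2 against 5.37% and 0.489% in WT1 and WT2. Col1a2 was highest in WT1, at 240 normalised CPM there and 28.9 in WT2 against 5.89 and 7.95 in DD1 and DD2.

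Within the epithelial-like class no gene passed the threshold in edgeR, and the genes with the smallest p lay in both directions. Lists of MHC class I (camera adjusted p = 0.0645), interferon response (0.0941) and CXC chemokine genes (0.0875) did not pass in this class. Tyrobp, an adaptor protein of myeloid cells, had a log2 fold change of −3.78 ± 0.47 (SE, n = 2 per genotype), H2-Aa, a class II chain, −3.09 ± 0.50, and Txnip, a thioredoxin-binding protein, −2.39 ± 0.37. Col9a1 (a mean of 184 normalised CPM in DD and 46.0 in WT), Rcan1, a calcineurin inhibitor (1.71 ± 0.35), and Snrpc (1.97 ± 0.43) had higher values, and the adjusted p of these 6 genes was 0.981 in edgeR. In DESeq2 Tyrobp (adjusted p = 2.76e-05), H2-Aa (1.79e-04), Txnip (0.00332) and Col9a1 (0.0499) passed, and Rcan1 (0.197) and Snrpc (0.100) did not. Rb1 had a log2 fold change of −0.89 and PYMT −0.16, which turned to 0.29 without WT2 and 0.02 without DD2. In barcodes under 300 counts Tyrobp was at 487 and 390 CPM in WT1 and WT2 and 114 and 142 in DD1 and DD2. Macrophage marker genes in the epithelial-like class stood at 1033 and 661 CPM in WT1 and WT2 against 283 and 481 CPM in DD1 and DD2, and fibroblast marker genes at 131 and 368 CPM against 21.5 and 102 CPM. Different clusters held most of the class in each library, with 43.0% in cluster 4 and 35.3% in cluster 2 for WT1, 68.5% in cluster 6 for WT2, 53.8% in cluster 5 and 42.3% in cluster 10 for DD1, and 31.4%, 28.4%, 16.8% and 16.7% in clusters 4, 6, 1 and 5 for DD2.

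edgeR called 0 of 13745 genes in the epithelial-like class, with 497 at an unadjusted p under 0.05, and DESeq2 called 42, 11 higher and 31 lower. The 497 genes are a smaller part of the 13745 than the 0.05 that unchanged genes would give. The edgeR count was 270 without DD1 and 1 without DD2, Spink8, chosen after its values were seen. In simulated data 11% of genes changed by 2 on the log2 scale and 58.0% of those changed by 3 were called, and 4.17% of the calls were false.

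Of the 24 lists measured in this class, 12 were called by camera, and 0 held with an estimated correlation. MHC class II genes were lower at an adjusted p of 3.01e-12 (0.390 with an estimated correlation), with H2-Eb1 at −2.71 and Cd74 at −1.99 and 5 passing adjusted over the list alone. Collagen and matrix genes were lower at 1.65e-11 (0.481 with an estimated correlation), with Sparc at −3.56, CC chemokines at 5.22e-08 (0.531 with an estimated correlation), with Ccl4 at −3.77, and alternative and inflammatory macrophage genes at 7.36e-08 and 7.71e-08 (0.390 and 0.531 with an estimated correlation), with Apoe at −3.42 and Il1b at −4.00. Basal keratin and contractile genes were lower at 5.59e-08 (0.390 with an estimated correlation), with Cnn1 at −4.50, and mesenchymal genes at 1.76e-04 (0.582 with an estimated correlation) and angiogenesis genes at 3.21e-04 (0.589 with an estimated correlation) followed. Hormone-sensing luminal genes, with Wnt4 at −1.86 and Esr1 at −1.45, were lower at 0.00197 (0.716 with an estimated correlation). Milk genes, with Btn1a1 at −1.64, were called at 0.0407 (0.531 with an estimated correlation), while Csn3 had a value of 1.25. Cytokines and colony factors were called lower at 0.0483 (0.658 with an estimated correlation) although their median was 0.13. Unfolded protein response genes were called higher at 0.0483 (0.808 with an estimated correlation), with Dnajb9 at 1.40 and Hspa5 at 0.85. Single libraries decided 6 of these calls. The adjusted p without DD1 was 0.575 for hormone-sensing (then higher), 0.614 for unfolded protein response (then lower), 0.374 for mesenchymal, 0.486 for cytokine and 0.259 for angiogenesis genes. Without WT1 it was 0.918 for cytokine, 0.363 for unfolded protein response and 0.272 for angiogenesis genes, and without WT2 0.664 for milk and 0.0618 for hormone-sensing genes.

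In the macrophage-like class, tested on 2369 and 330 cells of WT1 and WT2 and only 89 and 57 of DD1 and DD2, no gene passed in edgeR. Klra17, a receptor of the Ly49 family, had a log2 fold change of 3.23 ± 0.61 (SE, n = 2 per genotype), the chemokine Ccl5 2.34 ± 0.50 and the ribosomal protein gene Rps3a1 2.01 ± 0.44. Rps3a1 was at 169 and 267 normalised CPM in WT1 and WT2 against 584 and 1177 in DD1 and DD2, in the same order as in the barcodes under 300 counts, at 234, 360, 397 and 1324 CPM. Cxcl2, a neutrophil chemokine, had −1.73 ± 0.33 and PYMT −2.49 ± 0.53. PYMT held only 20 and 2 counts in DD1 and DD2, and Klra17 13 and 9. Sparc and Gas6 each had 1 count in DD; WT held 42.0 times (95% interval of counts 7.52 to 1663) and 20.6 times (3.68 to 817) the CPM. Sparc in the barcodes under 300 counts was at 778 and 507 CPM in WT1 and WT2 against 46.8 and 97.3 CPM in DD1 and DD2. All of these genes had an adjusted p of 0.343 in edgeR.

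edgeR called 0 of 3758 genes in this class, with 263 at an unadjusted p under 0.05, and DESeq2 called 5: Ccl5, Cxcl2, Klra17, PYMT and Rps3a1. Without DD1 the edgeR count was 72, without DD2 37 and without WT1 19. The PYMT transcript, from the oncogene behind these tumours, was at 608 and 692 CPM in macrophage-like cells of WT1 and WT2 and at 181 and 30.6 CPM in those of DD1 and DD2. In T cell-like cells it was at 739 and 1752 CPM against 145 and 430 CPM, where the DD1 and DD2 values rest on very few counts in 8 and 7 cells. PYMT was at 2353, 3798, 2802 and 2268 CPM in epithelial-like cells of WT1, WT2, DD1 and DD2. In barcodes under 300 counts it was at 2259, 2469, 2578 and 1186 CPM in the same order.

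**Figure D3:**
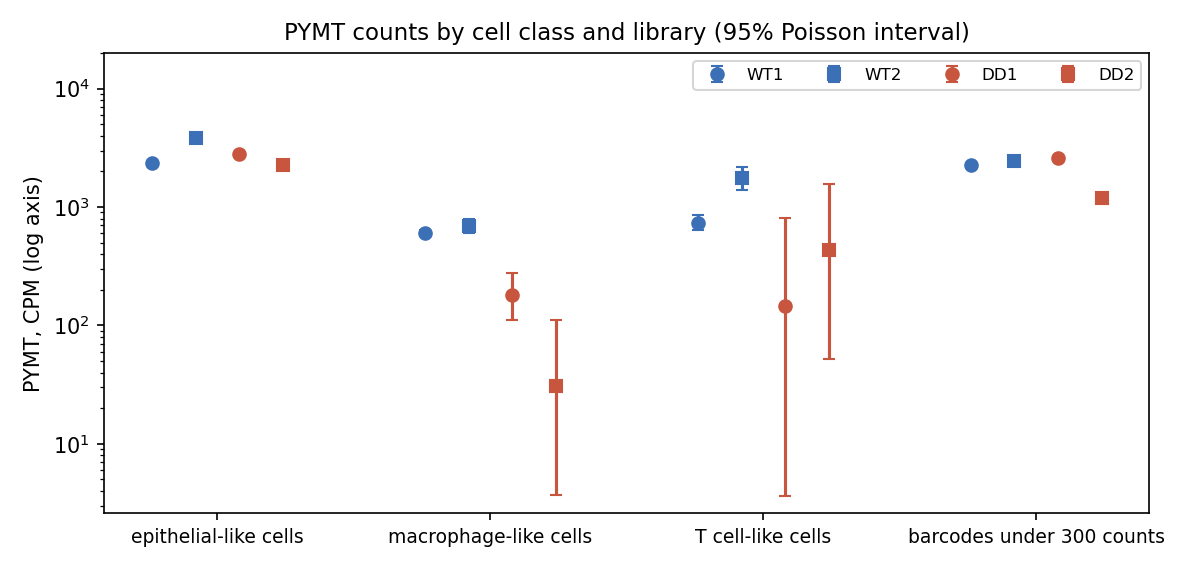
PYMT CPM (log axis) in epithelial-like, macrophage-like and T cell-like cells and in barcodes under 300 counts, 1 point per library with its 95% Poisson interval. In macrophage-like cells DD1 and DD2 (181 and 30.6 CPM, on 20 and 2 counts) lie below WT1 and WT2 (608 and 692 CPM), and epithelial-like cells lie above both. The T cell-like points of DD1 and DD2 rest on very few counts in 8 and 7 cells.

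Of 20 lists measured in macrophage-like cells, 7 were called by camera and 0 held with an estimated correlation. Epithelial adhesion genes, with Krt8 at −1.88 and Krt19 at −2.67, were lower at an adjusted p of 1.48e-06, luminal progenitor genes, with Ltf at −2.55, at 2.63e-05, and collagen and matrix genes at 1.17e-05, each with an adjusted p of 0.305 with an estimated correlation. Markers of other cell types were lower in the same cells, with luminal epithelial markers at 2450 and 1674 CPM in WT1 and WT2 against 716 and 674 CPM in DD1 and DD2, and fibroblast markers at 201 and 174 CPM against 9.06 and 45.9 CPM. Alternative macrophage genes were lower at 0.0351 (0.588 with an estimated correlation), with Gpnmb at −2.51 and Maf, in the other direction, at 1.03. Cluster 3, with Gpnmb and Trem2 among its leading genes, held 18.5% and 19.7% of macrophage-like cells in WT1 and WT2 and 8.99% and 10.5% in DD1 and DD2. Inflammatory macrophage genes were lower at 0.0173 (0.639 with an estimated correlation), with Il1a at −0.95. CC chemokines (adjusted p = 0.746, 4 of 9 higher) and CXC chemokines (0.0702) did not pass in camera. Cytosolic ribosomal protein genes were higher at 2.26e-04 (0.588 with an estimated correlation), with Rps2 at 1.18, and MHC class II genes at 0.0338 (0.588 with an estimated correlation), with Cd74 at 1.40. Mitochondrial transcripts in this class had a median of −0.71, with 7 of 10 lower, and did not pass (0.0702). The ribosomal protein gene Rps3a1 had higher values in DD in the barcodes under 300 counts as well. The MHC class II call was lost without WT1 (0.0959), DD1 (0.0916) and DD2 (0.233), the inflammatory call without WT1 (0.0937) and DD1 (0.106), the alternative call without DD2 (0.448) and the ribosomal call without DD2 (0.0974). T cell-like, fibroblast-like and neutrophil-like cells were too few in DD for a test within the class, with 8 and 7, 2 and 1, and 0 and 1 cells in DD1 and DD2.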

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

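The interaction test, the tests of PYMT and the tests of the immune shares were chosen only after the results were seen, while the limits for the share of interaction genes were set before that share was measured.

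The genotype difference itself differed between epithelial-like and macrophage-like cells for 225 of 13426 genes in an edgeR interaction test with Benjamini-Hochberg adjustment, 139 of them relatively higher and 86 relatively lower in macrophage-like cells of DD, with 1256 at an unadjusted p under 0.05. Ccl5, C1qa and Tyrobp, chosen after their values were seen, differed by 3.75, 3.83 and 3.71 on the log2 scale. The p-values of this fit treat the spread between libraries as almost known. Ccl5, at 3.75 ± 0.40 (SE), had an edgeR p of 4.79e-21 here. Gpnmb over all cells, at −5.23 ± 0.52, had an edgeR p of 7.22e-05 in the main test. No alternative was run for the interaction, so the 225 calls may be too many. Of the 225 genes, 83.1% were at least 2-fold more abundant, in the WT libraries, in the class whose DD value was relatively higher, which is consistent with free RNA of the other class as a candidate cause. The 2 parts were unlike, with 97.1% of the 139 and 60.5% of the 86, against 11.6% and 26.2% of all genes tested. The second part is thus not accounted for to the same degree, and an effect of genotype stays open and untested.

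PYMT in macrophage-like cells stood out because its genotype difference differed from that in epithelial-like cells by −2.65 ± 0.48 (log2, SE), with an edgeR adjusted p of 1.21e-05. That p-value has the limit given above for the interaction test. A level predicted from free RNA, taken from the PYMT share in barcodes under 300 counts and the counts of the barcode ranked 15000 (265, 124, 69 and 44 in WT1, WT2, DD1 and DD2), gave a log2 ratio of −2.10 against a measured −2.49 ± 0.53. The PYMT share alone had a DD to WT ratio of 0.796, so the prediction rests mostly on the ranked barcode. Only this rank was used, and in WT1 that barcode may not be an empty droplet, at 265 counts. Free RNA in the droplets may account for the ratio, but this comparison cannot settle it. The predicted levels were 504, 308, 143 and 45.5 CPM in WT1, WT2, DD1 and DD2 against 608, 692, 181 and 30.6 measured, so WT2 held more than predicted. The measured values of DD1 and DD2 rest on 20 and 2 counts. Uptake of tumour RNA by macrophages stays open, as does genotype. PYMT CPM in T cell-like cells was 1.21 and 2.53 times that in macrophage-like cells of WT1 and WT2. Equal free RNA in shallower T cell-like cells would alone give 1.40 and 1.31. This comparison takes T cell-like cells to make no PYMT of their own, which was not tested. T cell-like cells of DD1 and DD2 held too few PYMT counts for a ratio, 1 and 2.

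Cells lost under the count minimum were not shown to explain the lower share of macrophage-like and T cell-like cells in DD. A loss of cells under 300 counts was not excluded. Over all barcodes, with no minimum, the macrophage marker CPM in DD was 0.228 of that in WT, with both DD libraries below both WT libraries beyond their counting intervals. Kept cells supplied 73.1%, 47.8%, 72.8% and 59.0% of these counts in WT1, WT2, DD1 and DD2, and shallow cells add little, so this measure cannot decide. In the barcodes under 300 counts, the measure looked at before that of all barcodes, the macrophage marker ratio of DD to WT was 0.427, and 0.249 for T cell markers. Those barcodes thus held no excess of these markers in DD. A higher yield of tumour cells from DD tumours could lower both classes alike, and the T cell-like share of these classes had an exact permutation p of 0.667, so this cannot be told apart from a loss of immune cells with 2 against 2 libraries. Uniform dilution alone would leave the make-up of the macrophage-like class as it was, and the share in it of cluster 3, which also has the dendritic cell marker Ccr7, was 19.1% ± 0.824 in WT and 9.76% ± 1.09 in DD (SD, n = 2; exact permutation p = 0.333), on only 8 and 6 such cells in DD1 and DD2, whose Wilson intervals of 4.63% to 16.7% and 4.91% to 21.1% reach into those of WT2 (15.8% to 24.3%). Genotype stays open, as do differences between the samples that the labels do not give.

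In barcodes under 300 counts, outside the kept cells, luminal epithelial marker genes were higher in both DD libraries than in both WT libraries, with means of 7163 CPM ± 804 in DD and 5998 CPM ± 142 in WT (SD, n = 2). The cutoff took 4624, 14459, 12585 and 17003 barcodes of WT1, WT2, DD1 and DD2. Median counts over all barcodes were 429, 171, 163 and 66 in the same order. The sets are thus not alike, and which barcodes they hold was not set apart from genotype. Within epithelial-like cells the same markers overlapped, at 11514 and 12969 CPM in WT1 and WT2 against 7946 and 12462 CPM in DD1 and DD2.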

How the results depend on the processing

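The macrophage-like list tests and the setting without the highest 5% of doublet scores were added after seeing the data. The gene counts moved with the tool, the filter and single libraries. DESeq2 called 257 genes over all cells, 42 in the epithelial-like and 5 in the macrophage-like class where edgeR called 0, and without a low-count filter the counts were 655, 251 and 52. Thinned to the smallest library, 7 macrophage-like genes were called. Leaving out 1 library gave 0 to 702 genes over all cells, 0 to 270 in the epithelial-like and 0 to 72 in the macrophage-like class; with 3 libraries the lone sample of a genotype is assumed to vary like the other group. The replicate block gave 0 genes in each of the 3 classes, with 1687, 1233 and 452 at an unadjusted p under 0.05, and 13, 10 and 9 lists. Deviations of same-numbered libraries from their genotype means correlated with r of 0.34, 0.41 and 0.30. With 2 libraries per genotype both numbers give the same r by arithmetic. Replicate 1 also had the higher total counts in both genotypes, so r does not show that a number marks a shared batch. The cause of the differences between settings was not tested.

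With an estimated correlation 0 lists were called in any class, and without a low-count filter 15 were called in the macrophage-like class. Leaving out 1 library gave 12 to 16 lists over all cells, 10 to 15 in the epithelial-like and 5 to 9 in the macrophage-like class. In the epithelial-like class the hormone-sensing list (adjusted p 9.72e-19 to 0.575), the unfolded protein list (1.15e-04 to 0.614) and Hsp90b1 (log2 −0.29 to 1.30) turned direction without DD1. Over all cells PYMT turned to −0.37 without WT1 and −0.19 without DD1 (highest 0.63), and in the epithelial-like class to 0.29 without WT2 and 0.02 without DD2 (lowest −0.50). Plet1 in the macrophage-like class turned to 0.36 at Leiden resolution 0.5.

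All 60 alternatives for the 5 class shares kept their direction, in a design whose exact test cannot pass the threshold, but with a minimum of 300 counts the neutrophil-like shares no longer separated the genotypes (exact permutation p = 0.667). Leaving out 1 library gave macrophage-like differences of −26.9 to −12.8 percentage points, T cell-like −3.41 to −2.71, epithelial-like 16.2 to 37.8, fibroblast-like −5.27 to −0.394 and neutrophil-like −2.42 to −0.0963. Averaged over the replicate numbers, the paired differences, counted among the 60, equal the unpaired ones by arithmetic and test nothing more. By pair they were −29.4 and −10.3 for macrophage-like, −3.63 and −2.49 for T cell-like, 40.8 and 13.2 for epithelial-like, −5.31 and −0.356 for fibroblast-like and −2.48 and −0.0296 for neutrophil-like cells. For the share of epithelial-like cells with G2/M transcripts the paired differences were of opposite sign. The difference in the share of epithelial-like cells with G2/M transcripts was −5.90 with at least 1 count. It was −4.46 thinned to 1000 counts without the shallower cells, and −1.04 with a minimum of 300 counts and thinning to 300. Each had both DD libraries below both WT libraries. It turned to 0.281 with at least 3 counts, and ranged from −2.66 to 0.691 with 1 library left out, for causes that were not tested.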

Other observations

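The marker levels in barcodes under 300 counts and the list test in macrophage-like cells were chosen only after the data were seen, while the other tests were planned.

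Fibroblast, T cell, neutrophil and endothelial marker genes were also lower in both DD libraries in the barcodes under 300 counts, a set that is not alike between libraries. Fibroblast markers were at 614 and 455 CPM in WT1 and WT2 against 82.3 and 181 CPM in DD1 and DD2, and T cell markers at 211 and 198 CPM against 45.4 and 56.5 CPM. Neutrophil markers were at 1856 and 704 CPM against 211 and 356 CPM, and endothelial markers at 177 and 55.4 CPM against 12.5 and 44.3 CPM. Haemoglobin and other erythroid markers were at 4561, 1714, 288 and 2293 CPM in WT1, WT2, DD1 and DD2, so the genotypes overlapped, as they did for Schwann cell markers at 179, 173, 205 and 111 CPM, for skeletal muscle markers and for mast cell markers, which had at most 3 counts per library.

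Hmox1, the haem-degrading enzyme and a member of the oxidative stress defence list, had log2 fold changes of 2.65 ± 0.46 in epithelial-like and 2.31 ± 0.57 in macrophage-like cells (SE, n = 2 per genotype). The adjusted p was 0.981 and 0.385 in edgeR, which called it in neither class, and 0.0320 and 0.140 in DESeq2, which called it in epithelial-like cells. The list did not pass in camera, at an adjusted p of 0.117 and 0.590.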
